A study of Mus musculus with 8 samples.

How the data were processed

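Genomic DNA from the dorsolateral prefrontal cortex of wild-type aged mice of the outbred ICR stock was profiled with a MethylTarget library, an assay in which chosen regions are amplified by PCR from bisulfite-treated DNA and sequenced, so that the share of reads keeping a cytosine at a CpG gives its methylation. Per the labels' protocols, DNA was extracted with a rapid extraction kit for animal tissue, and the indexed PCR products of the samples were pooled at equal amounts, recovered as 1 library and checked for fragment length on a Bioanalyzer; the labels do not describe the bisulfite step itself. Bisulfite reads do not separate 5-methylcytosine from 5-hydroxymethylcytosine, a modification that is common in brain. The 8 samples fall into 2 groups of 4, kept on a campus (the control) or in a traffic tunnel (the polluted air). The titles number the samples 1 to 4 in each group and do not say that each is a separate animal; p-values measure the spread between these samples, which may be partly technical.

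The authors deposited, for each sample, 1 methylation fraction (0 to 1, not normalized) per CpG, together with the amplicon, the chromosome, the genome position and the distance to the transcription start site, per the file headers. Fractions are given below as percent methylation. Every file held the same 57 CpGs, from 4 amplicons in 2 genes, with 0 missing values. Genome builds mm10 and hg19 are both named in the submitters' processing notes, with no role; the positions lay in or directly beside the mouse genes that name the amplicons in the RefSeq table of GRCm38 (assembly mm10), and are given as mm10 positions counted from 1. The aligner, the methylation caller, read filters and the conversion rate are not given in the sources used here. No read counts or coverage accompanied the fractions, and depth was not worked out from the fractions themselves. No counting interval is therefore attached to any value, and a value listed at 0 is given without an upper limit. All 57 sites were CpGs, and cytosines outside CpGs, which would measure conversion, were not analysed here. The table used for gene positions gives no exons, so exon and intron assignments are not given.

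Each site was tested with limma 3.58.1 in R 4.3.3 on the arcsine square root of the fraction, with a mean-variance trend in the empirical Bayes step, group as the only term and all 8 samples in the fit; p-values were two-sided and Benjamini-Hochberg adjusted over the 57 sites, with a threshold of 0.05. For each amplicon, each gene and the whole panel, the unweighted mean over sites was taken per sample and the groups were compared with an exact two-sided permutation test of the difference in means over the 70 allocations of the 8 samples (Python 3.11.15, numpy 2.4.6). Its smallest possible p is 0.0286, and adjustment over the 4 amplicons gives at least 0.114 when a single amplicon reaches it. Intervals of a difference are the shifts that this exact test does not reject, with a coverage of 97.1%. Group values are mean ± SD over samples. The site test was tested on simulated data drawn for the 57 sites from their own means and spreads in 50 simulations per setting. A raised site kept the spread it had before, and sites were drawn independently of one another.

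The rule for named sites, the tests and the alternatives were fixed before the data were examined, except where stated. Every amplicon was named, with the 5 sites of smallest p if fewer than 5 passed the threshold, and the site with the largest group difference in each amplicon. Alternatives were the untransformed fraction, M values (log2 ratios of methylated to unmethylated fraction with 0.01 or 0.001 added), an exact test per site, limma without the trend, sites with a mean fraction of 0.02 to 0.98, samples centred on their own mean, medians and arcsine means over sites, means over amplicons, the replicate number as a block, and leaving out each sample in turn. The alternatives that need coverage or missing values did not apply. A filter at mean fractions of 0.1 to 0.9 left 0 sites. The 10 gene lists fixed beforehand (synapse and plasticity, inflammation, oxidative stress and xenobiotic response, amyloid and tau, DNA methylation machinery, and markers of neurons, astrocytes, microglia, oligodendrocytes, and endothelium and blood) held 0 of the 2 genes measured, so no list was tested.

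The shared replicate numbers showed no pairing of the samples. After group means were removed, the correlation across sites between same-numbered samples ranged from -0.39 to 0.05. Between campus and tunnel samples of different number it ranged from -0.24 to 0.35, so a weak pairing could have gone unseen. The 28 pairs of samples shared 0 identical site values, and their correlations across sites ranged from 0.71 to 0.88, so all 8 were counted as separate samples. The labels give no batch.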

Results

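CpG methylation was measured in the dorsolateral prefrontal cortex of aged mice kept on a campus (4 samples) or in a traffic tunnel (4 samples), to ask whether a real traffic environment was accompanied by altered methylation at 2 genes. The first was Abca7, which encodes a lipid transporter of the ATP-binding cassette family and is a risk locus for Alzheimer's disease. The second was Ptk2b, which encodes the calcium-responsive tyrosine kinase Pyk2, enriched in forebrain neurons, and is likewise a risk locus for that disease. Abca7 was covered by 37 CpGs in 3 amplicons on chromosome 10 (mm10). Amplicon 03 held 16 CpGs from 79996441 to 79996602, at -52 to +109 bp from the transcription start site given with the data. Amplicon 04 held 11 CpGs from 79997368 to 79997531 (+875 to +1038 bp), and amplicon 05 held 10 CpGs from 79997592 to 79997734 (+1099 to +1241 bp). The 2 most upstream CpGs of amplicon 03 lay outside the RefSeq gene and the other 35 Abca7 sites inside it. Ptk2b was covered by 1 amplicon of 20 CpGs on chromosome 14 from 66280829 to 66281023, at +29 to +223 bp from its start site and inside the gene. Read depth was not given for any site.

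All 4 amplicons were sparsely methylated in every sample, and no single value exceeded 8.78%. The mean over the 57 CpGs was 1.8% ± 0.101 (SD, n = 8), site means ran from 0.485% to 6.93%, and 43 of the 57 sites had a mean under 2%. The least methylated CpG was the Abca7 site at the start site itself, at 0.485% ± 0.331 (SD, n = 8). Within Abca7, amplicon 03 averaged 1.09% ± 0.0476 and amplicon 04 1.11% ± 0.0601 (SD, n = 8 each). By contrast, amplicon 05, whose first CpG lies 61 bp beyond the last CpG of amplicon 04, averaged 2.91% ± 0.372 (SD, n = 8). Amplicon 05 was above amplicon 04 in 8 of 8 samples, by 1.8 percentage points ± 0.359 (SD; exact two-sided sign-flip test, p = 0.00781, the smallest that 8 samples allow, adjusted p = 0.0117 over 3 amplicon pairs; a comparison chosen after the data were examined). The highest Abca7 sites were +1241 (6.93% ± 1.13), +1099 (5.49% ± 1.16) and +1177 (4.18% ± 1.09). In Ptk2b, which averaged 2.19% ± 0.186, the highest sites lay between +117 and +161 bp, with 4.82% ± 0.924 at +154, 3.82% ± 0.477 at +161 and 3.52% ± 0.678 at +117 (SD, n = 8).

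**Figure D1:**
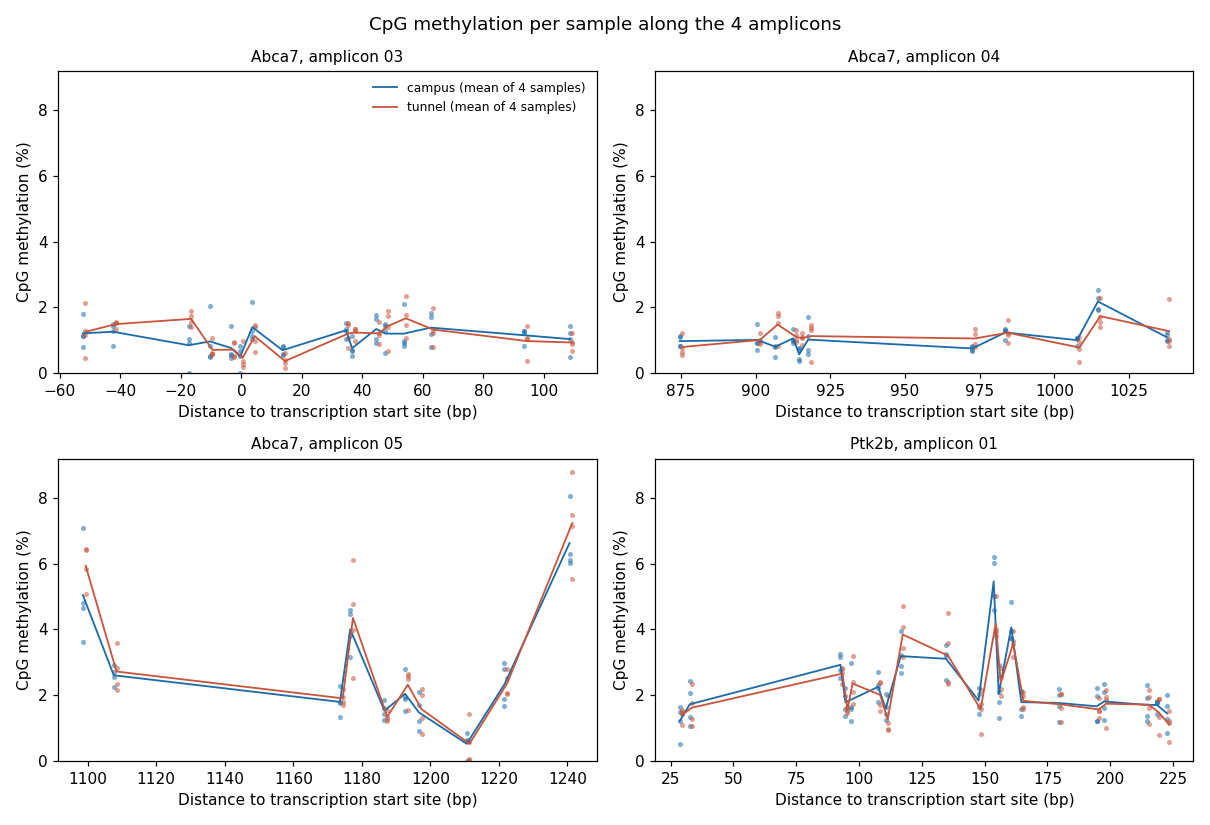
Methylation (%) of each CpG against its distance to the transcription start site (bp) in the 4 amplicons; points are single samples, lines join the group means of 4 samples, and the groups are drawn less than 1 bp apart for legibility. The campus and tunnel profiles follow each other, with the highest mean at +1241 bp in Abca7 amplicon 05 (6.93% over the 8 samples) and the Ptk2b maximum at +154 bp.

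No difference in Abca7 methylation between the tunnel and campus samples passed its test. Over its 37 CpGs, Abca7 averaged 1.53% ± 0.0654 in campus and 1.64% ± 0.121 in tunnel samples (SD, n = 4 each), a difference of 0.107 percentage points (exact 97.1% interval -0.0883 to 0.35; exact two-sided permutation p = 0.2, adjusted p = 0.4 over 2 genes). The difference was 0.0586 without tunnel replicate 3 and 0.157 without tunnel replicate 4 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0571). The tunnel mean was the higher at 21 of the 37 sites. Amplicon 04 had the smallest p of the 4 amplicons, with 1.06% ± 0.04 in campus and 1.15% ± 0.0436 in tunnel samples. The difference was 0.086 percentage points (interval -0.0244 to 0.167, exact permutation p = 0.0571, adjusted p = 0.229 over 4 amplicons). In this amplicon 3 of the 4 tunnel samples lay above every campus sample, and the tunnel mean was the higher at 6 of the 11 sites. The amplicon difference rested mainly on 2 CpGs, at +907 bp (0.675 points) and +915 bp (0.489 points). At the other sites of amplicon 04 the differences ran from -0.445 to 0.303 points. With 1 sample left out, the amplicon 04 difference ranged from 0.0688 (without campus replicate 1) to 0.107. The latter was without tunnel replicate 1 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.114). Relative to the mean of the other amplicons in the same sample, it was 0.0305 (exact permutation p = 0.771). That mean takes in amplicon 05 and Ptk2b, which spread more widely (SD over 8 samples 0.372 and 0.186, against 0.0601), so it cannot decide whether the difference is particular to amplicon 04. Amplicon 03, which spans the start site, was at 1.06% ± 0.0355 in campus and 1.11% ± 0.0514 in tunnel samples (difference 0.0457, interval -0.0588 to 0.14; exact permutation p = 0.2, adjusted p = 0.4), and the tunnel mean was the higher at 6 of its 16 sites. Its difference was 0.0282 without tunnel replicate 4, and -0.0232 relative to the mean of the other amplicons (exact permutation p = 0.886), a comparison with the same limit. Amplicon 05 was at 2.8% ± 0.233 and 3.03% ± 0.483, with a higher tunnel mean at 9 of its 10 sites (at +1211 bp by only 0.000674 points), and its difference of 0.229 points was smaller than the SD of the tunnel samples (interval -0.661 to 1.02; exact permutation p = 0.429, adjusted p = 0.571). That difference was 0.446 without tunnel replicate 4, 0.0733 without tunnel replicate 3, 0.15 without tunnel replicate 1 and 0.122 without campus replicate 1, and with the median over sites it was 0.0494 (exact permutation p = 0.886).

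The Abca7 CpGs named by smallest p or largest difference were all higher in tunnel samples, and none passed the limma test. The CpG at -17 bp (position 79996476) was at 0.848% ± 0.609 in campus and 1.65% ± 0.216 in tunnel samples, 1.95-fold (limma, adjusted p = 0.523). Campus replicate 2 was listed at 0 there, and without it the ratio was 1.46. The CpG at +907 bp (position 79997400) was at 0.803% ± 0.243 and 1.48% ± 0.456, 1.84-fold (limma, adjusted p = 0.523). The CpG at +915 bp (position 79997408), at 0.57% ± 0.213 and 1.06% ± 0.156, was the only one of the 57 whose groups did not overlap, where chance gives 2.86% of sites, or 1.63 of 57 (limma, adjusted p = 0.554). The CpG at +37 bp (position 79996530) was at 0.76% ± 0.255 and 1.24% ± 0.178, 1.63-fold (limma, adjusted p = 0.554). A relative difference of similar size went the other way at +14 bp (position 79996507, chosen after its values were seen), with 0.697% ± 0.135 in campus and 0.367% ± 0.188 in tunnel samples, a ratio of 0.526 (limma, adjusted p = 0.905). In amplicon 05 the largest absolute difference was at +1099 bp (position 79997592), with 5.04% ± 1.47 in campus and 5.94% ± 0.64 in tunnel samples (limma, adjusted p = 0.905). That difference of 0.895 percentage points was 0.417 without campus replicate 1 and 1.58 without campus replicate 3.

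No difference in Ptk2b methylation passed its test either. Its 20 CpGs averaged 2.25% ± 0.264 in campus and 2.14% ± 0.0616 in tunnel samples (SD, n = 4 each), a difference of -0.108 percentage points (interval -0.539 to 0.137; exact two-sided permutation p = 0.6, adjusted p = 0.6 over 2 genes). The tunnel mean was the lower at 13 of the 20 sites. The direction rested on 1 sample: campus replicate 2 averaged 2.64%, the other 7 samples lay between 2.09% and 2.23%, and without it the difference was 0.0235 percentage points. With all 8 samples, the Ptk2b difference relative to the mean of the Abca7 amplicons was -0.228 (exact permutation p = 0.114). That value takes in campus replicate 2 and was not computed without it. It also takes in amplicon 05, which spread widely (SD over 8 samples 0.372). The largest single difference of the panel was at the Ptk2b CpG at +154 bp (position 66280898), with 5.46% ± 0.773 in campus and 4.18% ± 0.555 in tunnel samples, -1.28 percentage points (limma, adjusted p = 0.554).

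**Figure D2:**
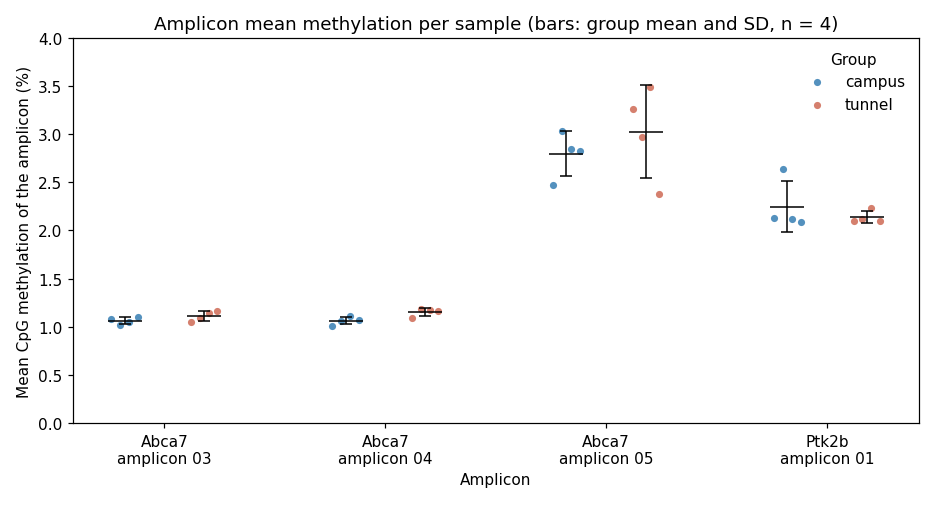
Mean CpG methylation (%) of each amplicon in each sample by group; black bars give the group mean and SD (n = 4). Amplicon 04 of Abca7 was at 1.06% in campus and 1.15% in tunnel samples, and 1 campus sample at 2.64% stands above the other Ptk2b values.

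Across the panel, limma called 0 of the 57 CpGs at an adjusted p of 0.05; the smallest adjusted p was 0.523. Unadjusted, limma gave 5 sites with p under 0.05 (4 higher and 1 lower in tunnel samples), against 2.85 expected by chance. The exact permutation test per site gave 1. That test goes under 0.05 only where the groups do not overlap, for which chance gives 1.63 sites, so the 2 counts are not on the same footing. The mean over all sites was 1.78% ± 0.117 in campus and 1.81% ± 0.0972 in tunnel samples (difference 0.0316 percentage points, interval -0.246 to 0.263; exact permutation p = 0.629), and 28 of the 57 sites had the higher mean in tunnel samples (exact permutation p = 1). With 1 sample left out, the panel difference ranged from -0.0106 (without tunnel replicate 3) to 0.0877 (without campus replicate 2), and it was -0.00336 without campus replicate 1. Among the 14 sites with a mean fraction of 0.02 to 0.98 the tunnel mean was the higher at 10 (exact permutation p = 0.486). In simulated data with 15 of the 57 sites raised in 1 group, the site test recovered 91.3% of the sites raised 2-fold and 34.5% of those raised 1.5-fold. With 3 sites raised it recovered 74.7% and 19.3%. Raised sites kept their spread in the simulation, whereas measured spread tended to be wider at more methylated sites, so these shares may be too high. Differences under about 2-fold at single CpGs were often not detectable with 4 samples per group.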

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

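The tests of campus replicate 2 in this part were chosen after its values were seen. Among the 24 sets of 4 samples examined (the amplicon means, the Abca7 mean, the panel mean and the 6 named CpGs, each in both groups), 4 held a sample far from the other 3 by Dixon's ratio; chance gives about 1 in 20, or 1.2 here. In the Ptk2b amplicon mean, campus replicate 2 was at 2.64%, against 2.09% to 2.13% in the other campus samples, and tunnel replicate 3 at 2.23%, against 2.1% to 2.12% in the other tunnel samples. In the Abca7 mean, campus replicate 1 was the lowest at 1.44%, against 1.56% to 1.58%. At the Abca7 CpG at +37 bp, tunnel replicate 2 was the lowest at 0.972%, against 1.29% to 1.35%.

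The Ptk2b mean of campus replicate 2 lay 0.513 percentage points above the mean of the other 7 samples. Incomplete conversion of the whole library would have lifted Abca7 by about as much, but its Abca7 mean lay -0.00879 points from that of the other 7 samples, whose SD was 0.115. A few stray sites do not account for it either, since this sample had the highest of the 8 values at 9 of the 20 Ptk2b sites. What stays open is few template molecules, in the Ptk2b PCR alone or in the whole sample, which the fractions cannot show. Campus replicate 2 held 2 of the 3 values listed at 0 in the panel, both in Abca7 amplicon 03. Another amplicon-specific cause, or a difference of that brain sample itself, also stays open and was not tested.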

How the results depend on the processing

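None of the 15 results (Ptk2b and its single amplicon counted once) passed an adjusted threshold of 0.05 under any alternative that was run. For the gene and amplicon means this is no sign of stability, since a single gene cannot go below an adjusted p of 0.0571 (reached by the Abca7 mean without tunnel replicate 4) nor a single amplicon below 0.114. The panel mean is a single test that could reach 0.0286. Its smallest exact permutation p with 1 sample left out was 0.229. Of the alternative values, 188 of 205 kept both direction and side of the threshold (a count, its size within 1.5-fold). The site test called 0 CpGs under all 16 of its alternatives, of which the exact test per site could call none unless 33 sites reached its smallest p. Sites with an unadjusted p under 0.05 numbered 5 in limma, 1 among the sites with a mean fraction of 0.02 to 0.98, 2 with the replicate number as a block, and 1 to 4 with 1 sample left out. By the exact test per site there was 1, but that test goes under 0.05 only where the groups do not overlap. No value that reversed passed its test in either direction, and the cause was not tested. Relative to the mean of the other amplicons, the difference was -0.0232 percentage points in Abca7 amplicon 03, 0.0305 in amplicon 04, 0.221 in amplicon 05 and -0.228 in Ptk2b (exact permutation p = 0.114). For amplicons 03 and 04 the wider spread of amplicon 05 and Ptk2b limits this comparison. Amplicon 05 gave 0.0494 with medians over sites and 0.378 over sites with a mean fraction of 0.02 to 0.98, and the panel 0.0631 as a mean of amplicon means and 0.0618 as a median. Of the sites, 10 of the 14 with a mean fraction of 0.02 to 0.98 had the higher tunnel mean (exact permutation p = 0.486), against 28 of 57. With 1 sample left out, the Ptk2b difference ranged from -0.159 to 0.0235 (above 0 without campus replicate 2), the panel mean difference from -0.0106 to 0.0877 (below 0 without campus replicate 1, at -0.00336, or tunnel replicate 3), and the sites higher in tunnel from 24 to 31. The Abca7 mean difference ranged from 0.0586 (without tunnel replicate 3) to 0.157 (without tunnel replicate 4, exact permutation p = 0.0286, the smallest possible), and that of amplicon 03 from 0.0282 (without tunnel replicate 4) to 0.0666. The replicate block changed no call in limma (0 sites), and for the means its exact sign-flip test over 16 sign patterns cannot go below p = 0.125, so it says nothing of their stability; 1 of the 8 samples correlated best with its own number. Depth is unknown, so sampling of reads or molecules cannot be separated from differences between samples.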

Other observations

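In this part, the tests of neighbouring sites, of covariation in Abca7 amplicon 05, of campus replicate 2 and of the unadjusted count over splits were chosen after the result was seen. The pattern of more and less methylated CpGs recurred between samples within each amplicon. The mean correlation of site profiles between samples was 0.914 over the 10 sites of Abca7 amplicon 05 (site means 0.521% to 6.93%) and 0.76 over the 20 Ptk2b sites (1.28% to 4.82%). It was 0.392 over the 11 sites of amplicon 04 (0.814% to 1.96%) and 0.329 over the 16 sites of amplicon 03 (0.485% to 1.43%). Each had a permutation p of 1e-05, the smallest that 100000 shuffles of sites within samples can give; sites are not independent replicates. A uniform background, such as conversion failing equally at all cytosines, gives every site 1 level and so cannot be the whole source of these levels in any of the 4 amplicons. Conversion or PCR that depends on local sequence stays open, because cytosines outside CpGs were not analysed here.

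Other divisions of the samples were compared with the real one. At an unadjusted p under 0.05 in limma the real division gave 5 sites, 5 of the 35 splits into 4 and 4 (itself included) gave as many, and the highest other was 7, so chance cannot be excluded. At an adjusted p of 0.05 the real count was 0, which all 35 splits reach by construction, so that comparison decides nothing; the highest other was 1. A hypothesis that the Abca7 CpGs at +907 and +915 bp mark a local rise was tested on the other CpGs within 6 bp of either (+901, +913 and +918 bp), whose mean was 1.03% ± 0.131 in campus and 1.08% ± 0.173 in tunnel samples (difference 0.0519 percentage points, exact interval -0.307 to 0.364, exact permutation p = 0.6). The upper bound lies below the 0.489 points at +915 bp, which argues only against a shared change as large as that estimate. The CpG at +915 bp was named for its small p in these same samples, so its estimate may be too large. Its own exact interval, 0.0781 to 0.861, overlaps that of the neighbours. A smaller rise shared by the cluster, a change at single CpGs and chance all stay open.

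A further hypothesis was that samples differ in the share of molecules methylated at several CpGs at once, so that sites of an amplicon vary together once group means are removed. The mean correlation between sites was 0.106 in Ptk2b (permutation p = 0.00898, adjusted p = 0.0359 over 4 amplicons), 0.167 in Abca7 amplicon 05 (permutation p = 0.0274, adjusted p = 0.0548), -0.0722 in amplicon 04 (p = 0.101 by permutation) and -0.0492 in amplicon 03 (p = 0.0856 by permutation). Only the Ptk2b value passed the correction, and without campus replicate 2 it was -0.0415 (permutation p = 0.08), so it rests on that sample. Whether exposure altered the spread between samples remained undecided, with a median log2 ratio of tunnel to campus SD over sites of -0.0801 (exact permutation p = 0.886).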
